A study of Homo sapiens with 2 samples.

How the data were processed

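RNA was measured in 2 samples of MCF-10A, an established, non-tumorigenic human mammary epithelial cell line, 1 stably expressing EGFP alone (the EGFP vector sample) and 1 stably expressing ARHGAP4 fused to EGFP. Per the labels' protocols, total RNA was extracted with a PureLink kit, amplified to sense-strand cDNA with the GeneChip whole-transcript kit, fragmented, labelled with biotin by terminal transferase and hybridised to Affymetrix arrays, 1 per sample. The 2 samples were grouped by the genotype given in their labels. There was 1 array per group, so no difference has a replicate check and no p-value, standard error or SD between replicates is given for any gene.

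The deposited table holds 1 normalized log2 expression value per feature (transcript cluster) and array for 44629 features. The scanner software, the summarisation, the normalization and their versions are not given in the sources used here. The log base is read from the values: the highest deposited value, 12.8, exceeds the natural log of a 16-bit scanner's highest reading, 11.1, and its log10, 4.82, which leaves log2. The table was used as deposited, with no further scaling in the main analysis. The 2 columns have nearly the same quartiles, as they would after a common scaling before deposit, which the sources do not state. Such scaling would remove any overall difference in RNA content, so all differences below are read as relative to the bulk of the features. In 3106 features (6.96%) both arrays hold the same value to the last digit. The number of arrays limits the precision; no detection calls were used.

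Gene names came from the platform annotation of 2020 supplied with the table, which gave 1 symbol to 15835 features, several symbols to none and no symbol to 28794. All 15835 entries matched a gene of the GRCh38.p14 RefSeq gene table by Entrez identifier. The genome build behind the array table is not given, so no coordinates are printed; the gene table was used only for names, for chromosomes and for the order of neighbouring genes. Log2 values of features that share a symbol were averaged, giving 14812 genes, of which 14161 rest on 1 feature. Among the 336 genes past the level filter with several features, the pooled SD of the difference within a gene was 0.21 and the median range 0.19. These describe agreement between features on the same 2 arrays, not between cultures.

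Differences are EGFP-ARHGAP4 minus EGFP vector on the log2 scale. The level filter kept a gene when the higher of its 2 values was at or above 4.02, the median of all gene-level values, and 7685 genes passed. Genes were counted as different at a log2 difference of 1 (2-fold) either way; members of gene lists were also counted at 0.5. For each of 36 gene lists, the median difference of all measured members was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list outside the 2.5 to 97.5 percentile range was called standing apart, as a description of these 2 arrays. Of 33 lists with at least 5 measured members, 1.65 would stand apart by chance if genes differed independently. The integrin subunits, the replication-dependent histones and the mitochondrially encoded genes had no named feature and were not analysed here. The values of 1 further list are not reported here. Older symbols in the lists were matched through the synonyms of the gene table. Several lists were measured only in part, and each result covers the measured members alone.

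The lists, the thresholds, the level filter and the rule for named genes were fixed before the data were examined. The rule named ARHGAP4, and the 12 genes with the largest and the 12 with the smallest difference among those past the level filter. It left out small RNAs, unnamed or non-coding loci such as LINC symbols, and olfactory receptors by the start of the symbol. It also named up to 4 members with the largest absolute difference from each list that stood apart. The same held for the RhoGAP, RhoGEF, septin, integrin, focal adhesion and actomyosin lists. From any other list it named up to 2 members with a difference of at least 1. A few further genes are named after their values were seen, and this is said where they appear. For the order along chromosomes, medians over windows of 25 neighbouring genes past the filter were compared with 1000 shuffles of the differences over positions, and a single step was fitted on chromosome 10 by least absolute deviations.

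Alternatives were quantile normalization of the 2 arrays, centring on the median difference, removal of a loess curve of difference on mean level (span 0.3), other level filters, other thresholds, the feature with the highest mean level in place of the mean, unmatched random lists and, chosen after seeing the data, leaving out the genes of chromosome 10. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9. The calculations were tested on simulated data with the spread of the real differences at each level. Of 50 genes simulated at each size for this comparison, the 2-fold count took 3 at 1.5-fold, 20 at 2-fold, 48 at 3-fold and 50 at 4-fold, and it took 4 of 7485 unchanged genes. In the simulated lists, 2 of 33 stood apart with no change and 33 of 33 with all members 0.5 higher. This simulation knows only the spread between genes, and holds no variation between cultures. Its differences were normal and centred on 0, with an SD taken from the median absolute deviation. The tails of the real differences were thus left out, so the 4 of 7485 is no rate of false calls for these arrays.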

Results

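Whole-transcript arrays were used to compare MCF-10A mammary epithelial cells that stably expressed ARHGAP4, a GTPase-activating protein, fused to EGFP with cells that expressed EGFP alone. The design holds a single comparison, with 1 array of each line, and asks which transcripts differ when the fusion protein is expressed. The median log2 expression value over the 44629 features was 2.88 in both arrays, and the third quartile was 4.66 in the EGFP vector array and 4.60 in the EGFP-ARHGAP4 array. Across features the 2 arrays correlated with r = 0.987, and across the 7685 genes past the level filter with r = 0.966; genes are not independent replicates. All differences are between these 2 arrays, without replicates, and cannot be set against variation between cultures.

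ARHGAP4 itself, on the X chromosome, had a log2 value of 4.49 in the EGFP vector array and 6.68 in the EGFP-ARHGAP4 array. The difference of 2.19, or 4.56-fold, was among the 12 largest of all genes past the filter and went in the direction of the sample labels. It rested on 1 feature. Which part of the transcript that feature covers, and how much of the signal came from the introduced sequence, is not given in the sources used here.

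Of the 7685 genes past the filter, 77 were at least 2-fold higher and 61 at least 2-fold lower in the EGFP-ARHGAP4 array, and 85.0% differed by less than 0.5 on the log2 scale. The median difference of these genes was -0.10. Of the genes called, 55.8% were higher as deposited, 67.2% after quantile normalization of the 2 arrays and 68.9% after removal of the level trend. At 1.5-fold the balance was the reverse, with 277 higher and 495 lower. The highest difference was that of ALOX5AP, the 5-lipoxygenase activating protein of leukotriene synthesis, at 4.44 against 8.24, a 14.0-fold difference. SRGN, the proteoglycan serglycin of secretory granules, stood at 2.61 against 6.13. ANKRD1, a stress-responsive ankyrin repeat protein, was 5.69-fold higher, and KDR, a receptor for vascular endothelial growth factor, was 4.83-fold higher. LAMP3, a lysosomal membrane protein, was 4.82-fold higher and LAPTM5, a lysosomal membrane protein known from blood cells, 4.13-fold higher. The chemokine CCL20 differed by 2.05 on the log2 scale and the secreted stress cytokine GDF15 by 2.06. MCF2, a guanine nucleotide exchange factor, differed by 2.16. The zinc finger genes ZNF284 and ZNF320 differed by 2.06 and 2.01; both have close paralogs whose RNA the feature could share. SRGN, ANKRD1, KDR, MCF2, ZNF284 and ZNF320 lay below the level filter in the EGFP vector array, where differences narrow towards background, so their folds are approximate.

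The lowest difference was that of KRT14, a keratin of basal epithelial cells, which stood at 9.21 in the EGFP vector array and 6.96 in the EGFP-ARHGAP4 array, 4.76-fold lower. Its sequence is close to that of other type I keratins, so its value is uncertain to the extent that the feature takes up their RNA. NRP1, a co-receptor for semaphorins and vascular endothelial growth factor, was 3.81-fold lower and DOCK11, an exchange factor for CDC42, 3.62-fold lower. ARHGAP21, a GTPase-activating protein of the same family as ARHGAP4, was 2.94-fold lower, and MCM10, a DNA replication factor, 2.58-fold lower. The others among the 12 lowest were HSPA14, PTER, CPPED1, ZFP69, GTPBP4, SVIL-AS1 and CUL2, at differences between -1.32 and -1.53. The naming rule left out LINC00707, a non-coding locus of chromosome 10, which was at -1.89. NRP1, DOCK11, ZFP69 and SVIL-AS1 lay below the level filter in the EGFP-ARHGAP4 array, so their folds are approximate as well. The same holds for genes named below with a value under the filter in either array, among them WFDC2, S100A4, CXCL8 and HPSE. Of these 12 genes, 8 lie on chromosome 10 (NRP1, ARHGAP21, HSPA14, PTER, MCM10, GTPBP4, SVIL-AS1 and CUL2), and so do SRGN and ANKRD1 among the 12 highest.

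**Figure D1:**
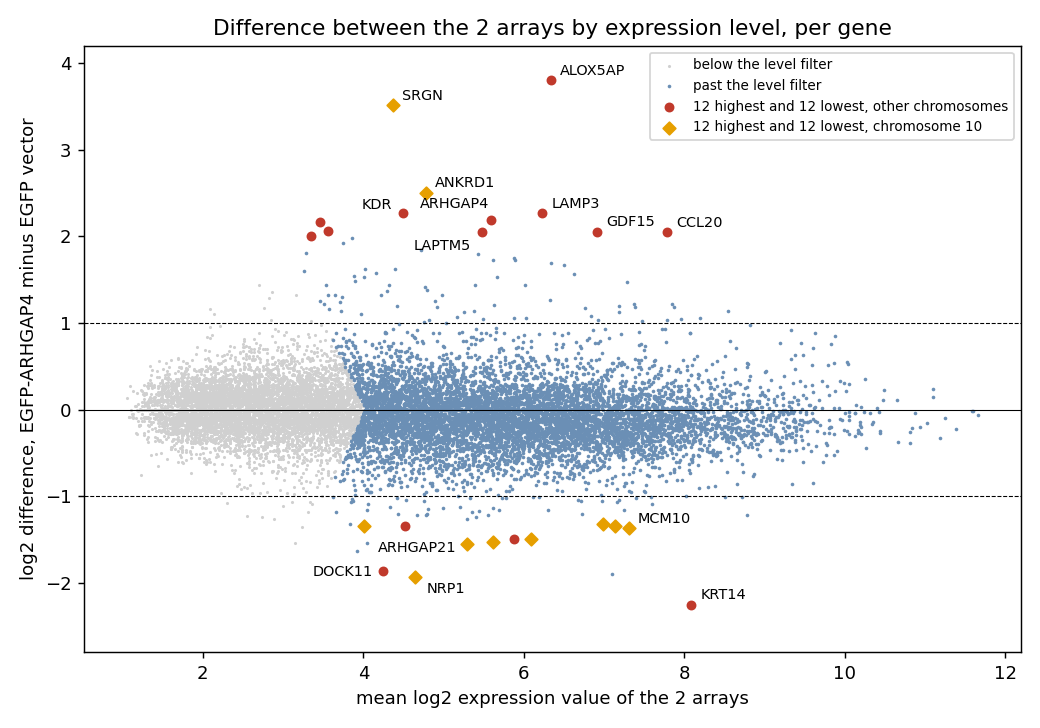
Each point is a gene, with the mean log2 expression value of the 2 arrays on the horizontal axis and the log2 difference, EGFP-ARHGAP4 minus EGFP vector, on the vertical axis; dashed lines mark 2-fold. The 12 highest genes reach 3.80 (ALOX5AP), the lowest is KRT14 at -2.25, and 8 of the 12 lowest are diamonds, which mark chromosome 10.

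Genes known as targets of the tumour suppressor p53 were higher in the EGFP-ARHGAP4 array. Of 30 listed targets 17 were measured, while CDKN1A and MDM2 had no named feature. The median of the 17 was 0.80 higher, or 1.74-fold, and 16 of 17 were above 0. A log2 difference of at least 0.5 was found for 12 of them, and none was lower by that much. GDF15 was 4.16-fold higher, TP53INP1, a regulator of autophagy and cell death, 3.47-fold, the oxidoreductase gene TP53I3 2.41-fold, and EDA2R, a receptor of the tumour necrosis factor family, 2.32-fold. The list median lay above every one of 10000 matched random lists, and none of the members lies on chromosome 10.

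Cell cycle genes were lower. Of 32 measured mitotic genes, 30 were below 0 and 18 were lower by at least 0.5, with a median of -0.53. KIF23, a kinesin of cytokinesis, was 1.84-fold lower, the kinetochore gene NDC80 1.78-fold, the spindle checkpoint kinase gene BUB1 1.75-fold and the cytokinesis exchange factor gene ECT2 1.75-fold. Of 27 measured genes of S phase and DNA replication, 26 were below 0 and 9 were lower by at least 0.5, with a median of -0.40. MCM10 was the lowest of these, followed by the replicative helicase gene MCM6 at -0.77, GINS2 at -0.73 and the transcription factor gene E2F1 at -0.70. Both medians lay below every matched random list, whose own medians centred on -0.12 for each list. No mitotic gene reached 2-fold, and in the replication list only MCM10 did.

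The measured inflammatory genes were mostly higher. Of 37 genes in the NF-kB and inflammatory list 23 were measured, with NFKBIA, TNFAIP3 and IL6 not among them. The 23 had a median of 0.44, 10 were higher by at least 0.5, and none was lower by that much. Only 15 of the 23 passed the level filter, 12 of them above 0 and 3 below. CCL20 was 4.14-fold higher, the acute phase gene SAA1 1.90-fold and the neutrophil chemokine gene CXCL8 1.86-fold, and the cytokine gene IL24 was 1.32 higher on the log2 scale; SAA1 has a near-identical neighbour, SAA2, so its feature can share signal. The 27 immediate early and ERK output genes had a median of 0.13, at the 99.9 percentile of random lists. Here EGR3 was 0.80 higher, DUSP1 0.55 and FOS 0.53, while KLF6, which lies in the lower part of chromosome 10 described below, was at -0.55. The 28 interferon response genes had a median of 0.19, also at the 99.9 percentile. Only 11 of them passed the level filter, and over those 11 the list no longer stood apart, at the 85.8 percentile. TRIM22 alone reached 2-fold, at 2.60-fold higher.

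The 27 epithelial junction genes had a median of 0.13, above 99.9% of random lists. Of these, 6 were higher by at least 0.5 and none lower: the tight junction gene CLDN7 was 2.33-fold higher, the epithelial adhesion gene EPCAM 2.30-fold, CLDN1 1.96-fold and the desmosomal cadherin gene DSG3 1.64-fold. Keratinocyte differentiation genes had a median of 0.21 over 36 members, above every random list, but only 11 passed the level filter. Among those, LCE3D was 0.93 higher and GRHL3, a transcription factor of epidermal differentiation, 0.74, while SPRR2A was at -1.06. Most of the 36 lie on chromosomes 1 and 19, which also hold windows of higher genes. Whether such regional differences enter this median was not tested. The 9 measured basal and myoepithelial markers, of 22 listed and without TP63 or KRT17, did not stand apart, with a median of 0.06. KRT14 was the only one at 2-fold. Its partner keratin KRT5, named here after its value was seen, differed by 0.02. The 22 luminal markers did not stand apart either, with a median of 0.04, and WFDC2 was 3.07-fold higher. The 15 mesenchymal genes had a median of -0.19, at the 7.52 percentile, or 40.8 without chromosome 10, with FSTL1 at -1.24 and S100A4 at 1.32. Of 44 listed extracellular matrix genes 18 were measured, with no collagen or laminin gene among them. Their median was 0.14, at the 99.0 percentile. FN1, fibronectin, was 2.09-fold higher, followed by LTBP2 at 0.79, BGN at 0.60 and HSPG2 at 0.52. Matrix proteases and their inhibitors centred on -0.05 over 26 genes, a median that changed sign after quantile normalization or loess, with ADAM8 2.89-fold higher and the heparanase gene HPSE 2.30-fold lower.

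The 42 measured members of the RhoGAP family other than ARHGAP4 had a median of -0.09, at the 20.4 percentile, or 3.59 among members past the filter, and 5 were lower by at least 0.5 while none was higher by that much. After ARHGAP21 the lowest were ARHGAP11A at -0.70, ARHGAP29 at -0.67 and ARHGAP31 at -0.62. The 42 RhoGEF genes had a median of -0.11, at the 13.9 percentile, with 4 higher and 4 lower by 0.5. DOCK11, ECT2, NET1 at -0.75 and ARHGEF39 at -0.66 were the lowest. NET1, like ARHGAP21, lies in the lower part of chromosome 10. MCF2, an exchange factor that this list leaves out, was higher by 2.16. None of the 12 septins differed by 0.5. Among septins past the level filter the largest differences were SEPTIN6 at -0.37, SEPTIN10 and SEPTIN11 at -0.32 and SEPTIN3 at 0.25; SEPTIN2 at -0.18 and SEPTIN9 at 0.22 are added after their values were seen.

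Integrin subunits were not analysed here. The 36 focal adhesion genes had a median of 0.02 and a mean of -0.02, opposite in sign, against -0.10 for the centre of their matched random lists. That placed the median at the 97.7 percentile, just outside the range, and it fell inside after quantile normalization, at 95.3, and without chromosome 10, at 94.4. The scaffold gene GIT1 was 0.74 higher, while RSU1, an integrin adhesion adaptor in the lower part of chromosome 10, was at -1.002, KANK2 at -0.67 and the kindlin gene FERMT2 at -0.66. Of 39 listed actomyosin and stress fibre genes 18 were measured, while ACTB, MYH9, FLNA and the ROCK genes had no named feature. The measured 18 did not stand apart, with a median of -0.19 at the 10.3 percentile. The formin gene DIAPH3 was 2.24-fold lower, the tropomyosin genes TPM4 and TPM2 were at -0.50 and -0.44, and LIMK2, a kinase that acts on cofilin, was at 0.57. ANKRD1 belongs to the lists of SRF and of YAP targets, but neither list stood apart, with medians of 0.05 over 14 genes and -0.01 over 13. The latter changed sign after quantile normalization, centring or loess.

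**Figure D2:**
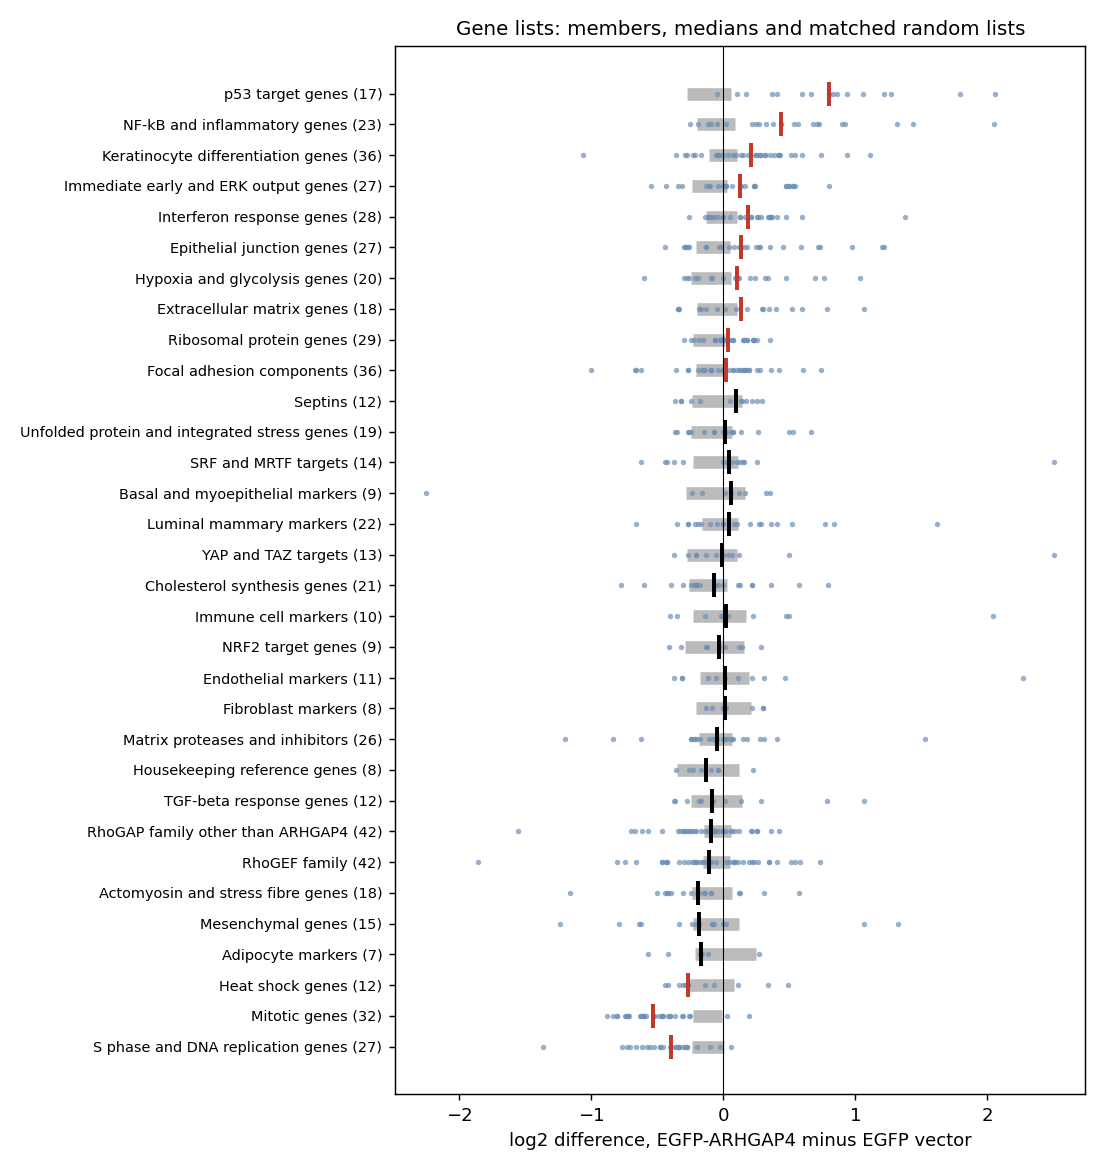
For each gene list (measured members in parentheses), points are the members' log2 differences, EGFP-ARHGAP4 minus EGFP vector, the vertical mark is their median (red where it stands apart) and the grey bar spans the middle 95% of medians of 10000 matched random lists. The p53 targets lie farthest to the right of their bar, at 0.80, and the mitotic genes farthest to the left, at -0.53.

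Among the remaining lists, hypoxia and glycolysis genes had a median of 0.10 at the 99.3 percentile, with BNIP3L, a mitophagy receptor, 2.05-fold higher, DDIT4 at 0.76, ADM at 0.69 and HK2 at -0.60. Of its 20 members, 5 lie on chromosome 10, and without those the list was at the 55.4 percentile. Heat shock genes had a median of -0.27 over 12 genes at the 2.34 percentile, and fell inside the range in 5 of 7 alternatives, at the 3.27 percentile after quantile normalization and 5.27 among members past the filter; HSPH1 was at -0.44 and STIP1 at -0.42, but BAG3 at 0.49 and HSPB1 at 0.34. Ribosomal protein genes had a median of 0.03 over 29 genes at the 98.7 percentile, or 89.3 when the random lists were not matched on level, none differing by 0.5, with RPS19 at 0.35, RPL19 at 0.25, RPL6 at -0.25 and RPS23 at -0.30. TGF-beta response genes (median -0.08), cholesterol synthesis genes (median -0.07), unfolded protein and integrated stress genes (median 0.01) and NRF2 targets (median -0.03) did not stand apart. The NRF2 median changed sign after quantile normalization or loess, and the cholesterol median after loess. The 8 housekeeping reference genes had a median of -0.13, at the 47.6 percentile, and none differed by 0.5. Markers of other cell types did not stand apart: the median was 0.01 for 8 fibroblast genes, 0.02 for 11 endothelial genes, 0.02 for 10 immune genes and -0.17 for 7 adipocyte genes. In the endothelial list KDR alone reached 2-fold, and in the immune list LAPTM5 alone. In all, 13 of the 33 lists stood apart, 10 above and 3 below, where 1.65 would by chance if genes differed independently. Genes expressed together and lists that share members break that assumption. The 1.65 is therefore no chance level for a comparison of 2 cultures.

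The differences were not spread evenly over the chromosomes. On chromosome 10 the 307 genes past the filter fell into 2 parts by their order. The first 71 genes, from DIP2C to ZNF37A, had a median of -0.82 (quartiles -1.03 and -0.61), 1.77-fold lower. The other 236, from LINC00999 to MTG1, had a median of 0.27 (quartiles 0.08 and 0.48). Genes of the other chromosomes had a median of -0.11. The first part held 23 of the 61 genes at least 2-fold lower, 37.7% of them, among them KIF5B at -1.21, named after its value was seen. Without chromosome 10, 68 genes were at least 2-fold higher and 38 at least 2-fold lower. The p53, mitotic, S phase and inflammatory lists stood apart without chromosome 10 too. The p53 list has no member there, and the S phase and inflammatory lists have 1 each. For these lists little could change beyond the random lists.

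**Figure D3:**
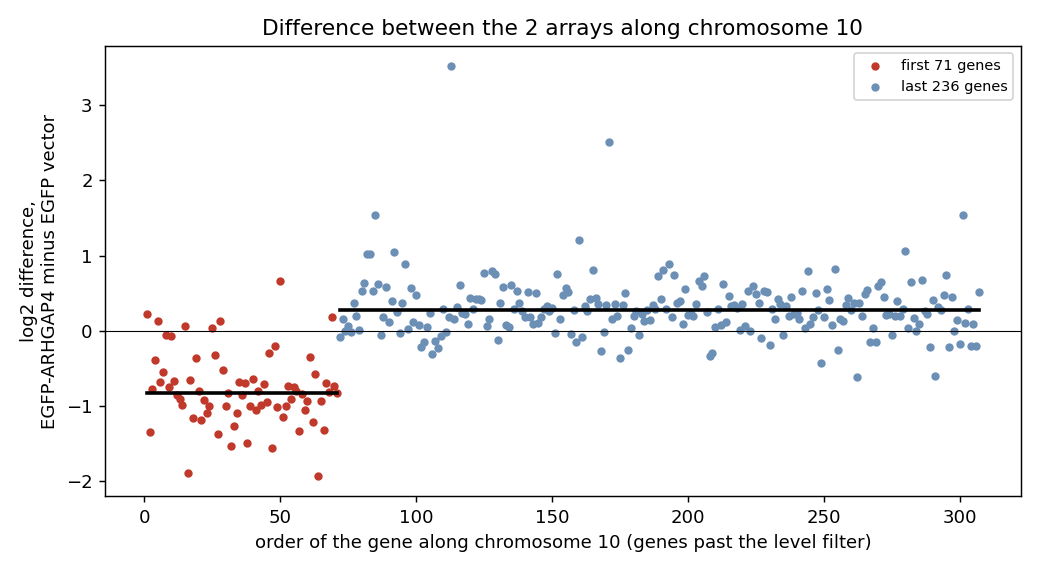
Genes of chromosome 10 past the level filter are plotted in their order along the chromosome (horizontal axis) against the log2 difference, EGFP-ARHGAP4 minus EGFP vector (vertical axis); black lines are the medians of the 2 parts. The first 71 genes centre on -0.82 and the other 236 on 0.27, with the change between ZNF37A and LINC00999.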

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

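Features without a gene name in the annotation used here entered none of the gene comparisons above, and they also differed between the arrays. Of the 6444 such features at or above the level filter in at least 1 array, 66 were at least 2-fold higher and 92 at least 2-fold lower in the EGFP-ARHGAP4 array. Feature 17100771 stood at 3.88 in the EGFP vector array and 7.498 in the EGFP-ARHGAP4 array, and feature 17081027 at 4.35 and 7.90. The lowest were feature 16695388, at 4.21 and 1.64, and feature 16801196, at 5.23 and 3.003. With 1 array per group, no group was large enough to look for a sample far from the others.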

How the results depend on the processing

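The difference in ARHGAP4 ranged from 2.19 to 2.28 over quantile normalization, centring, loess and the choice of feature, and none of the 95 named genes changed sign under these 4 settings. The scalings moved the median of all genes by 0.03 or less and that of genes past the filter by up to 0.10. The 77 genes at least 2-fold higher became 39 with the level filter at the 0.75 quantile, 277 at 1.5-fold and 25 at 3-fold; the 61 lower genes became 35, 495 and 5. Leaving out chromosome 10, chosen after seeing the data, left 38 lower genes. Under quantile normalization and under loess 42 genes were lower, and all 42 were among the 61. The number of lists standing apart lay between 10 and 13. Of the 13 lists, 8 stood apart under all 7 alternatives. The focal adhesion list no longer did after quantile normalization (median 0.098 above that of random lists), loess (0.105), without matching on level (0.053) and without chromosome 10 (0.099). The heat shock list no longer did after quantile normalization (-0.158), loess (-0.144), with the highest feature (-0.163), among members past the filter (-0.147) and without chromosome 10 (-0.159). Neither did the interferon list among members past the filter (0.134), the hypoxia list without matching (0.136) or without chromosome 10 (0.011), and the ribosomal list without matching (0.067). The actomyosin list stood apart only without matching, at -0.154. The causes were not tested. Pseudocounts did not apply to log2 values. Below the level filter the differences narrow towards the array's background, so folds of genes that start or end there are not exact.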

Other observations

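Of the tests below, the shuffles of gene order and the immune marker and leukocyte gene tests were chosen after the result was seen.

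Zinc finger genes near the end of chromosome 19 were higher in the EGFP-ARHGAP4 array. A run of 74 neighbouring genes past the filter, from MYADM to CENPBD2P, had a median of 0.41. The 40 zinc finger genes in it had a median of 0.45, and 17 of them were higher by at least 0.5. The 34 other genes of the run had a median of 0.31. Zinc finger genes elsewhere on chromosome 19 had a median of 0.03 over 67 genes, and those of other chromosomes -0.09 over 206.

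The chromosome 10 pattern is the most extensive in these data. Lower windows past the 5th percentile of the shuffles, -0.40, also lay on chromosomes 1, 6, 9, 12 and 14, in shorter runs. The shuffles treat neighbouring genes as independent, so their range may be too narrow. The lowest median of a 25-gene window was -0.94, on chromosome 10, whereas the lowest in any of 1000 shuffles was -0.48. The permutation share was therefore 0.001, the smallest the shuffles can give. Chance arrangement of independent genes is not a sufficient account. A level-dependent offset between the arrays is not one either, since the gap between the 2 parts was 1.09 as deposited and 1.11 after the loess curve was removed. A candidate explanation is a difference in copy number of the chromosome segment between the 2 lines, which would lower nearly all expressed genes of the first part. In that part 87.3% of genes lay below the median of all genes past the filter, between the 90% set as the bound for this explanation and the 75% set against it, so it stays open; above the 0.75 quantile of levels, looked at afterwards, 33 of 34 did, and 89.8% of the rest of the chromosome lay above that median. Both parts were themselves fitted to these differences. DNA was not measured, and the arrays cannot say which line differs from the parental cells or whether the construct has any part in it.

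For the run on chromosome 19, cross-hybridization among zinc finger genes at large would raise zinc finger genes of other chromosomes too. Their median lay only 0.0082 above that of all genes past the filter. Signal shared only among close paralogs within chromosome 19 would leave other chromosomes unchanged, so this test cannot decide on it. A copy number difference would raise the other genes of the same run, and their median lay 0.41 above that of all genes past the filter. The run was picked for its high window medians, though, and these genes helped to set them, so the value is no support and the explanation stays open. The whole of chromosome 19 was 0.13 above that median, so a property of the chromosome as a whole, such as base composition, which was not tested here, may account for part of the pattern. No biological explanation tied to the construct was tested.

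ALOX5AP, SRGN and LAPTM5 are known from blood cells and were among the 12 highest genes. Blood or immune cells in the EGFP-ARHGAP4 sample would bring their other abundant transcripts as well. The 9 other measured immune markers had a median difference of 0 and went both ways. CSF1R, from below the level filter, differed by 0.496 and CD68, the most abundant, by 0.48, while CD14 differed by -0.35 and TYROBP by -0.41; these members are named after their values were seen. A first bound on these markers, that the most abundant not be higher, was not met because of CD68 and left the explanation open. A second test, added after that, took genes that nearly all leukocytes express. They were listed before their values were read for this test, though DOCK2 was already a member of the RhoGEF list. The 15 measured of 20 listed had a median difference of 0 (quartiles -0.09 and 0.31), below the bound of 1. LCP1 was higher by 1.67 and EVI2B by 0.71, while CD53, CD37 and CD52 differed by 0, -0.07 and -0.19. These too are named after their values were seen. Only 3 of the 15 genes passed the level filter, LCP1 and EVI2B among them. How features near background respond to added RNA was not tested. The set did not rise as a whole, but admixed leukocytes are not excluded as a source of ALOX5AP, SRGN and LAPTM5. Whether the construct, selection of the line or its growth state raised them was not tested.

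The lower cell cycle genes and higher p53 targets form a joint pattern for which the design offers no test with 1 array per line. Without the chromosome 10 genes the mitotic list, which has 5 members there, differed by -0.46 from the median of its matched random lists. The p53 list median lay 0.92 above that of its own random lists. No p53 list member lies on chromosome 10, so only those random lists could change. Both list medians lay outside all 10000 random lists.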
